A study of Homo sapiens with 12 samples.

How the data were processed

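Gene expression was measured in 12 RNA samples of Flp-In T-REx 293 cells, a derivative of the human embryonic kidney line HEK293 that carries a site for single-copy transgene insertion and a tetracycline repressor, so that a transgene is switched on with doxycycline. Per the labels, 3 clones carried a TET1 transgene (A, F and G) and 3 carried a TET3 transgene (A, B and C). Each clone was sampled 48 h after induction and without induction, which gives 4 groups of 3 arrays. Per the labels' protocols, biotin-labelled cRNA was made from 200 ng of total RNA treated with DNase and was hybridised to 1 array per sample. A control line without a transgene was not analysed here.

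The authors deposited 1 signal per probe set and array as a linear intensity, and the submitters' processing notes name MAS5 for this step. Its version and the detection calls were not given in the sources used here. The deposited intensity values had a 2% trimmed mean of the same size on all 12 arrays (the largest was 1.00001 times the smallest), so the authors' scaling was kept. Median signals per array lay between 114.1 and 132.5. For arrays, the number of arrays limits the precision, and no depth in counts exists.

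The table held 54675 probe sets. The 62 control probe sets of the manufacturer were left out of all tests, which left 54613. Probe sets were named from the annotation table of the series: 41091 had 1 gene symbol, 1801 had several and 11721 had none, and no gene was named from a probe set with several. Symbols were updated with a RefSeq gene table of assembly GRCh38.p14, used for names only. Signals were tested as log2(signal + 16), so fold changes are on that scale and understate the change of dim probe sets. Probe sets above their own array's median in at least 3 of the 12 arrays were tested, which were 30191.

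The samples, contrasts, gene lists and most alternatives were fixed before the data were examined, and some tests and alternatives were added later and are named as such where they are used. limma 3.58.1 in R 4.3.3 fitted the 4 group means to all 12 arrays, with lmFit and eBayes with an intensity trend (8 residual degrees of freedom), and Benjamini-Hochberg adjusted p-values were called at 0.05. The 5 contrasts were induced minus uninduced in the TET1 clones, the same in the TET3 clones, the TET3 effect minus the TET1 effect, the mean of both effects, and uninduced TET3 clones minus uninduced TET1 clones. Every adjusted p given for a gene is limma's. At an unadjusted p of 0.05, 1510 of the 30191 tested probe sets are expected without any change. Probe sets annotated to TET1, TET2 or TET3 were to be kept whatever the filter, but all passed it, and their adjusted p-values are those over the 30191 tested.

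Each clone gave 1 induced and 1 uninduced array, so the clone pairs the samples. The deviations of the paired arrays from their group means correlated at 0.206, 0.315 and 0.146 in TET1-A, TET1-F and TET1-G. In TET3-A, TET3-B and TET3-C they correlated at 0.208, 0.0902 and 0.0864. These deviations were also compared between arrays of the same transgene and the opposite induction state. In that comparison, all 12 arrays were closest to the other array of their own clone. Arrays of the same group were not compared in this way. The fit without the clone was chosen as the reported one in advance, and the fit with the clone as a block (4 residual degrees of freedom) as its alternative. The contrast between uninduced clones lies between clones and has no blocked form. The labels do not say that the cultures of a clone were separate from each other beyond the induction. P-values of the reported fit measure the spread between these clones. Those of the blocked fit measure the spread of the induction effect between them.

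A total of 38 gene lists were tested with limma's camera at a preset correlation of 0.01, each gene represented by its brightest tested probe set (13377 genes), with adjustment over the 38 lists. They covered DNA demethylation and methylation, imprinted, germline and developmental genes, stress responses, metabolism, the cell cycle, DNA repair, immune genes, signalling pathways and markers of 6 other cell types. The same test was run with a correlation estimated from the data. Member counts are given over all probe sets tested and, where stated, adjusted over the list alone.

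The genes to be named were set by rule: every TET probe set; for each induction, up to 12 genes per direction past the threshold that moved the same way in all 3 clones, filled to 10 with the smallest p among those moving the same way by at least 1.5-fold; at most 8 per direction for the other contrasts, without filling; and from each list up to 4 members with the smallest p and up to 8 past the threshold. Genes outside this rule are named as chosen after their values were seen.

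The alternatives were the clone as a block, pseudocounts of 1 and 64, quantile normalization, median centring, no filter, a stricter filter (upper quartile), no intensity trend, 1 probe set per gene, array weights, only the arrays of the groups compared, each array and each clone left out in turn, the block with quantile normalization, and for lists an estimated correlation and the mean of a gene's probe sets.

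The fits were tested on simulated data made from these arrays, with 200 of the 30191 probe sets changed in the TET3 induction. The fit of group means called 29.9% of those changed 1.5-fold, 49.3% of those changed 2-fold and 81.8% of those changed 4-fold, and the blocked fit called 43.3%, 64.2% and 87.9%. Unchanged probe sets called were 1 in the first and 3 in the second. The simulated noise was independent between probe sets, whereas genes of the arrays are correlated (estimated at 0.75 for cytosolic ribosomal proteins). These counts therefore do not show how many calls in the real data are false. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.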

Results

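TET1 and TET3 are dioxygenases that oxidise 5-methylcytosine in DNA. The series title gives the question as the effect of overexpressing either enzyme on the transcriptome of HEK293 cells. Expression was measured on 12 arrays, with 3 clones carrying TET1 and 3 carrying TET3, each with and without induction for 48 h. The first principal component held 29.3% of the variance and placed all 6 TET1 arrays on one side and all 6 TET3 arrays on the other. The median correlation between arrays was 0.978 within a clone, 0.975 within a group and 0.962 between clones of different transgenes.

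The TET3 transgene was seen by 1 of the 3 TET3 probe sets. It rose from a mean signal of 548.1 ± 216 (SD, n = 3) in uninduced TET3 clones to 5412 ± 492 (n = 3) after induction, a log2 fold change of 3.34 (SE 0.42, adjusted p = 0.02, 0.0024 with the clone as a block and 0.032 with no filter), in 3 of 3 clones. The same probe set read 10.96 ± 5.02 in uninduced and 37.44 ± 42.8 in induced TET1 clones (n = 3 each). The uninduced TET3 clones were thus already higher than the uninduced TET1 clones, by 4.33 on the log2 scale (SE 0.42, adjusted p = 3.8e-05). The other TET3 probe sets did not pass on TET3 induction. The brighter of them read 1903 ± 268 without and 1534 ± 91.1 with induction (log2 -0.30, SE 0.11, adjusted p = 0.64), and the dimmer 179.9 ± 31.6 and 152.4 ± 17.9 (log2 -0.21, SE 0.28, adjusted p = 0.96). In the TET1 clones, neither TET1 probe set rose. The dimmer read 936 ± 233 without and 609.6 ± 64.4 with induction (log2 -0.58, SE 0.26, adjusted p = 0.83). The brighter read 2954 ± 236 and 2591 ± 303 (log2 -0.19, SE 0.12, adjusted p = 0.91). The arrays therefore give no reading of the TET1 transgene, and the labels alone identify the induced TET1 samples. A probe set outside the coding sequence does not detect a transgene made from that sequence alone, and the positions of these probe sets were not used here. Of the TET2 probe sets none passed on either induction, and the brightest moved by log2 0.12 (SE 0.15, adjusted p = 0.99) in TET1 clones and 0.16 (SE 0.15, adjusted p = 0.93) in TET3 clones. The call on the TET3 transgene was lost with a pseudocount of 1 (adjusted p = 0.10) and without an intensity trend (adjusted p = 0.20). It was also lost without the induced array of TET3-A, TET3-B or TET3-C (adjusted p = 0.12, 0.24 and 0.10) and without the uninduced array of TET3-B or TET3-C (0.13 and 0.15). Without both arrays of TET3-A, TET3-B or TET3-C it was 0.21, 0.54 and 0.45. The log2 fold change lay between 3.04 and 3.54 in these fits.

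**Figure D1:**
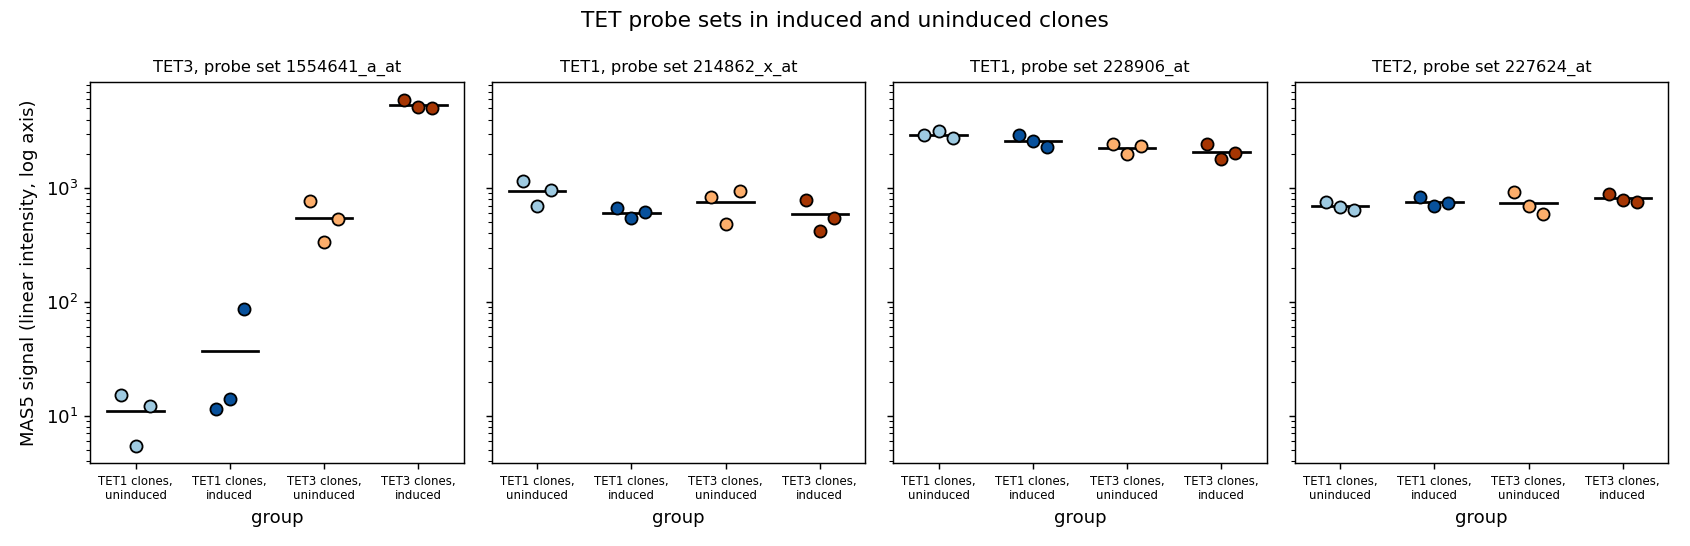
MAS5 signal (linear intensity on a log axis) of 4 TET probe sets, with 1 point per array and a line at the mean of each group of 3. The TET3 probe set that rose stands at 5412 in induced and 548.1 in uninduced TET3 clones against 10.96 in uninduced TET1 clones, while the TET1 and TET2 probe sets overlap between induced and uninduced arrays or are lower after induction.

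Beyond the transgene, TRAPPC6A, a subunit of a vesicle tethering complex, was higher after TET3 induction. Its mean signal went from 922.2 ± 162 to 1837 ± 137 (n = 3 each), a 1.99-fold change with log2 0.995 (SE 0.13, adjusted p = 0.02). With the clone as a block, which compares each clone with itself, 221 probe sets passed, 113 higher and 108 lower after induction. Among the genes that rose in that fit were RAB40B by 0.65 (log2, SE 0.06, adjusted p = 0.0015) and ALDH6A1, an enzyme of valine breakdown, by 0.74 (adjusted p = 0.0055). Further ones were TMEM205 by 0.81 (0.0069), RUNDC3B by 0.68 (0.0055), MPV17L2 by 0.68 (0.024), DACT3, an inhibitor of Wnt signalling, by 1.19 (0.025), and WIPI1, which acts in autophagosome formation, by 1.12 (0.0092). Those that fell were SPDEF, an epithelial transcription factor, with log2 -2.19 (adjusted p = 0.037), the stearoyl-CoA desaturase SCD with -0.70 (0.0079), PDLIM2 with -0.79 (0.0055) and the mitochondrial co-chaperone DNAJC15 with -0.78 (0.025). So did the matrix proteins EFEMP1 with -0.88 (0.01) and MFAP2 with -0.80 (0.01), the chromatin remodeller CHD3 with -1.58 (0.048), FBXO6 with -0.71 (0.023) and LINC01000 with -0.68 (0.05). PLPP4, with log2 -0.70, did not pass in either fit (adjusted p = 0.27, and 0.067 with the block). Several of these genes moved the same way in each TET1 clone too, thus in 6 of 6 clones. TRAPPC6A, ALDH6A1, RUNDC3B, MPV17L2, DACT3 and WIPI1 were higher, and PDLIM2, DNAJC15, EFEMP1, MFAP2 and PLPP4 lower. No doxycycline-treated line free of transgenes was analysed, so an effect of doxycycline on these genes cannot be told apart from one of TET3. Without the block, TET3 and TRAPPC6A were the 2 probe sets past the threshold out of 30191, with 1980 at an unadjusted p of 0.05. In that fit RAB40B, TMEM205, ALDH6A1 and PDLIM2 had an adjusted p of 0.064. Other probe sets of CHD3, SPDEF and LINC01000 did not follow, with log2 changes of 0.06 for CHD3, -0.34 and 0.71 for SPDEF and 0.00348 for LINC01000 (adjusted p of at least 0.93), and the brightest of SCD stood at -0.21 (adjusted p = 0.52). That count of 2 was 0 without the induced array of TET3-B or TET3-C, the uninduced array of TET3-C, or both arrays of any TET3 clone. It was 1 without the induced array of TET3-A, the induced array of TET1-G or clone TET1-G. It was 4 without the uninduced array of TET3-A or the induced array of TET1-F, and 6 without clone TET1-F. TRAPPC6A lost its call without an intensity trend (adjusted p = 0.20), with only the arrays of the TET3 clones (0.079) and without clone TET1-A (0.061), and in those fits without an array or clone that gave a count of 0 or 1. The blocked count of 221 was 58, 27 and 12 without clone TET3-A, TET3-B and TET3-C.

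Gene groups moved by small amounts in the TET3 clones. Genes of the endoplasmic reticulum unfolded protein response shifted upward: 26 of 31 members were higher, with a median log2 change of 0.15 (camera adjusted p = 2.6e-06; adjusted p = 0.14 with an estimated correlation). Examples are the stress sensor kinase EIF2AK3 at 0.41 (SE 0.12, adjusted p = 0.45), the translocon subunit SEC61B at 0.20 (SE 0.06, adjusted p = 0.50) and SELENOS, which acts in the removal of misfolded proteins, at 0.22 (SE 0.07, adjusted p = 0.50). The sensor ATF6 went the other way, at -0.32, and fell with the clone as a block (adjusted p = 0.048). Cholesterol and fatty acid synthesis genes shifted upward, with 21 of 28 members higher and a median of 0.09 (adjusted p = 0.001; adjusted p = 0.14 with an estimated correlation). Adjusted over the list alone, 5 rose and 1 fell. The sterol enzymes NSDHL and MSMO1 rose by 0.64 (adjusted p = 0.0068) and 0.37 (adjusted p = 0.039) with the block. Interferon-stimulated genes shifted downward, with 26 of 34 members lower and a median of -0.23 (adjusted p = 0.001; adjusted p = 0.14 with an estimated correlation). With the block 2 of them fell, among them the antiviral membrane protein IFITM2 at -0.86 (adjusted p = 0.0055), and PARP14 stood at -1.03 (adjusted p = 0.45, block 0.087). HOX genes, which set positional identity, shifted downward in 21 of 25 members with a median of -0.16 (adjusted p = 7.7e-04; adjusted p = 0.14 with an estimated correlation), for example HOXD1 at -0.80 (SE 0.23, adjusted p = 0.45) and HOXC4 at -0.29 (SE 0.09, adjusted p = 0.50). No member of these lists passed over all probe sets without the block, and adjusted over the list alone none of the unfolded protein response, interferon or HOX members did. These 4 lists kept their call and direction in all 27 other settings at the preset correlation. The ratio of 3' to 5' signal of the ACTB control, which reads RNA quality, was 1.94 ± 0.04 in uninduced and 2.02 ± 0.021 in induced TET3 clones (n = 3 each), higher after induction in 3 of 3 clones.

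The remaining 5 lists shifted downward on TET3 induction with smaller margins. The first was keratinocyte and HeLa-type epithelial markers (9 of 10 lower, median -0.17, adjusted p = 0.013; adjusted p = 0.15 with an estimated correlation). The others were Wnt targets and inhibitors (23 of 31 lower, 0.022), TGF-beta targets and extracellular matrix (33 of 48 lower, 0.023), metallothioneins and zinc handling (9 of 12 lower, 0.04) and developmental transcription factors (58 of 82 lower, 0.048). For these last 4 the result was adjusted p = 0.14 with an estimated correlation. Adjusted over the list alone, 2 keratinocyte markers fell, and of the TGF-beta list 1 rose and 2 fell. With the block the epithelial genes KRT19 at -0.37 (adjusted p = 0.025) and CAV1 at -0.29 (0.036) fell. The matrix genes TIMP1 at -0.33 (0.033) and LAMB1 at -0.29 (0.043) fell, and the receptor TGFBR1 rose by 0.35 (0.021). Metallothioneins MT1X at -0.25 and MT2A at -0.20 (adjusted p = 0.68 and 0.74) did not pass. Neither did the Wnt genes WNT5B at -0.41 and LEF1 at -0.23 (0.59 and 0.61), nor the developmental regulators NKX2-1 at -0.995 and PAX2 at -0.82 (0.31 and 0.38). With the block 4 more lists passed, namely ATF4 targets (upward, adjusted p = 0.027), mitochondrially encoded genes (upward, 0.037), histone genes (downward, 0.033) and kidney epithelium markers (downward, 0.037). Without it they had 0.063, 0.071, 0.22 and 0.062. With the block and an estimated correlation they had an adjusted p of 0.51, 0.54, 0.23 and 0.24. Single genes past the threshold with the block included OGT, the glycosyltransferase that binds TET proteins, up by 0.55 (adjusted p = 0.028), the p53 antagonist MDM2 at -0.32 (0.028), HLA-DPA1 at -0.57 (0.024), the histone gene H2BC12 at -0.39 (0.01) and the mitochondrially encoded ND2, up by 0.38 (0.026). In the hypoxia and glycolysis list 2 members rose and 1 fell with the block. The epithelial list lost its call without the induced array of TET3-A (adjusted p = 0.091). The Wnt and TGF-beta lists lost theirs without either array of TET3-A or without clone TET3-A or TET3-C. The metallothionein list lost its call without either array of TET3-A or TET3-B, the induced array of TET1-A or clone TET3-A or TET3-B. Over all settings at the preset correlation these 3 reached an adjusted p of 0.15, 0.14 and 0.17. Without the induced array of TET3-A, 5 lists passed in place of 9. The developmental list kept its call in 14 of 27 settings (highest adjusted p 0.36). It lost it with quantile normalization, with no filter and without clone TET1-G, TET3-A or TET3-C. Single arrays that ended it were either array of TET1-A or TET3-A, the induced array of TET1-G and the uninduced array of TET3-C. Another split of these 6 arrays that separated every clone's pair gave 10 lists against the real 9.

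TET1 induction moved no probe set past the threshold, with limma calling 0 of 30191 and 1770 at an unadjusted p of 0.05. The lowest adjusted p belonged to CNTNAP2, a neuronal cell adhesion gene, which read 625.2 ± 122 without and 258.5 ± 17.6 with induction (n = 3 each, log2 -1.21, SE 0.17, adjusted p = 0.15, or 0.059 with the block), lower in 3 of 3 clones. Others with higher signal after induction in all 3 clones were SVIP, an inhibitor of endoplasmic reticulum-associated degradation (log2 1.09, SE 0.19, adjusted p = 0.48) and YIPF4 (0.76, SE 0.12, adjusted p = 0.40). The same holds for the mitochondrial tyrosyl-tRNA synthetase YARS2 (0.77, SE 0.14, adjusted p = 0.48), adenosine kinase ADK (0.69, SE 0.15, adjusted p = 0.59) and WIPI1 (0.81, SE 0.19, adjusted p = 0.59). The remaining genes named by rule all had an adjusted p of 0.59. LRRC14, DHRS4-AS1, BCORL1, NENF and the small heat shock protein HSPB8 had higher signals, with log2 changes of 0.59, 2.16, 0.81, 1.69 and 0.92. FASTK, NFRKB, the RNA helicase DHX9, SERTAD4, FAM124A, TMTC3, the glutamyl-prolyl-tRNA synthetase EPRS1, FGF17 and CLIP1 had lower ones, with -0.72, -0.76, -0.63, -0.78, -1.73, -0.60, -0.62, -1.59 and -0.95. These values hold for 1 probe set per gene. Other probe sets of YIPF4, ADK, LRRC14, BCORL1, NENF, HSPB8, SERTAD4, FAM124A, TMTC3 and CLIP1 included at least 1 with the opposite sign. With the clone as a block 1 probe set passed, rising from 6137 ± 742 to 8979 ± 1.16e+03 (log2 0.547, adjusted p = 0.012). It has no symbol and was chosen after its values were seen. In the blocked fit 3361 probe sets had an unadjusted p under 0.05 for TET1 induction, against 3813 for TET3 induction.

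Gene lists also shifted by small amounts in the TET1 clones. Mitosis genes of the G2/M phase were higher in 50 of 68 members, with a median log2 change of 0.07 (camera adjusted p = 4e-04; adjusted p = 0.88 with an estimated correlation). Examples are the kinetochore gene NUF2 at 0.22 (SE 0.08, adjusted p = 0.79) and RACGAP1, needed for cytokinesis, at 0.14 (SE 0.06, adjusted p = 0.82). ATF4 targets of the integrated stress response were higher in 39 of 51 members with a median of 0.10 (adjusted p = 0.0018; adjusted p = 0.88 with an estimated correlation). Among them were the transcription factor ATF5 at 0.64 (SE 0.18, adjusted p = 0.64) and the translation repressor EIF4EBP1 at 0.25 (SE 0.09, adjusted p = 0.79). Mitochondrially encoded genes were higher in 5 of 7 members (median 0.18, adjusted p = 0.04; adjusted p = 0.88 with an estimated correlation). Of these 2 rose adjusted over the list alone. Cytosolic ribosomal protein genes were lower in 49 of 52 members with a median of -0.09 (adjusted p = 1.3e-13; adjusted p = 0.88 with an estimated correlation). This direction turned with quantile normalization, where the call was lost (adjusted p up to 0.85). Nuclear-encoded oxidative phosphorylation genes were lower in 50 of 68 members with a median of -0.04 (adjusted p = 0.016; adjusted p = 0.88 with an estimated correlation). That call was lost with quantile normalization and with median centring. Except for those 2 mitochondrial genes, no member of the 5 lists passed over all probe sets or adjusted over the list alone. The ACTB ratio was 2.31 ± 0.12 in uninduced and 2.14 ± 0.04 in induced TET1 clones (n = 3 each), lower after induction in 3 of 3 clones. The 5 lists became 2 without the uninduced array of TET1-A, the uninduced array of TET1-G or clone TET1-G. The ATF4 list lost its call without the induced array of TET1-F or the uninduced array of TET1-A or TET1-G, and the G2/M list without the induced array of TET1-G, the uninduced array of TET1-F or clone TET1-G. The mitochondrially encoded list lost its call without either array of TET1-G, the induced array of TET1-F, the uninduced array of TET1-A or clone TET1-F, TET1-G or TET3-A. The oxidative phosphorylation list lost its call without the induced array of TET1-F, the uninduced array of TET1-A or TET1-G, or clone TET1-A or TET1-G. Over all settings their adjusted p reached 0.46, 0.75, 0.43 and 0.90.

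**Figure D2:**
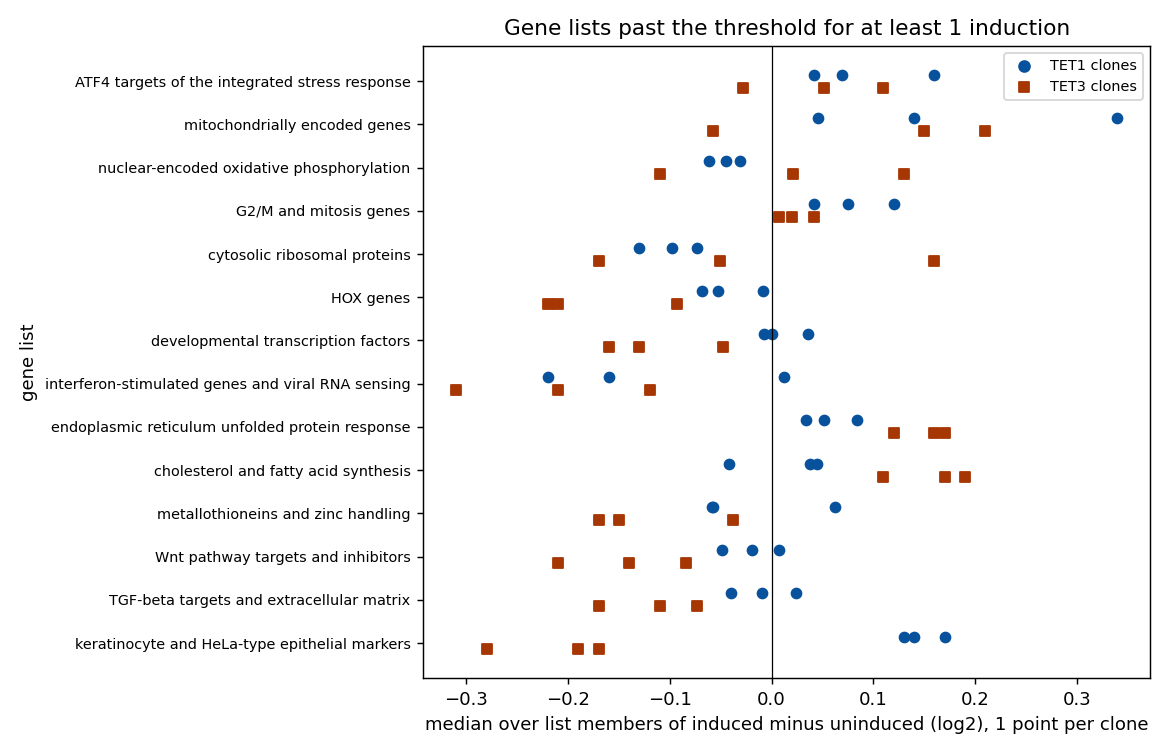
Median log2 change (induced minus uninduced) of each gene list past the threshold for at least 1 induction, with 1 point per clone, circles for the 3 TET1 clones and squares for the 3 TET3 clones. Unfolded protein response genes lie above 0 in all 6 clones, at 0.12 to 0.17 in the TET3 clones. Cytosolic ribosomal protein genes lie below 0 in all TET1 clones, at -0.17 in TET3-B and at -0.051 in TET3-C, but at 0.16 in TET3-A.

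Several lists tied to the function of the TET proteins did not pass on either induction. HOX genes and developmental transcription factors, given above, passed for TET3 and not for TET1 at the preset correlation. Of the genes on the array, the filter left 26 of 39 imprinted, 10 of 59 germline, 7 of 34 protocadherin and 11 of 23 pluripotency genes. Most germline, protocadherin and pluripotency genes were thus not tested. The adjusted p was 0.97 for TET1 and 0.89 for TET3 induction for the 27 tested genes of active DNA demethylation and base excision repair, 0.70 and 0.24 for DNA methylation maintenance and readers, 0.79 and 0.73 for imprinted genes, 0.70 and 0.73 for germline and cancer-testis genes, 0.22 and 0.22 for clustered protocadherins and 0.82 and 0.20 for pluripotency genes. The p53 target list gave 0.23 and 0.20, DNA double strand break repair 0.87 and 0.82, and neuronal genes 0.85 and 0.68. Over all lists that did not pass, adjusted p lay between 0.063 and 0.99 for TET1 (33 lists) and between 0.062 and 0.89 for TET3 (29 lists).

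Averaged over both transgenes, 8 probe sets passed, 6 higher and 2 lower after induction. WIPI1 rose by 0.96 on the log2 scale (SE 0.14, adjusted p = 0.042), TRAPPC6A by 0.69 (SE 0.09, adjusted p = 0.042), RUNDC3B by 0.57 (SE 0.08, adjusted p = 0.042) and ALDH6A1 by 0.47 (SE 0.07, adjusted p = 0.045), each in 6 of 6 clones. DNAJC15 fell by 0.68 (SE 0.10, adjusted p = 0.042) and the zinc transporter SLC39A6 fell by 0.36 (SE 0.06, adjusted p = 0.048), again in 6 of 6 clones. The rule for naming required this, so it is no further evidence. The other calls were the TET3 probe set (adjusted p = 0.042, and 0.056 with no filter) and a probe set shared by RNF5 and its pseudogene. With the clone as a block 437 probe sets passed, 247 higher and 190 lower. Among these were the cholesterol synthesis genes HMGCS1, up by 0.37 (adjusted p = 0.0027), and NSDHL, up by 0.40 (0.0091). The unfolded protein response genes XBP1, up by 0.28 (0.014), and SEL1L, up by 0.29 (0.033), passed too, as did the mitochondrially encoded ND2, up by 0.34 (0.0086), and ATP6, up by 0.31 (0.014). Genes that fell in this fit included HLA-DPA1 at -0.42 (adjusted p = 0.016), the p53-linked MDM2 at -0.20 (0.033) and PMAIP1 at -0.18 (0.043), and 2 members of the demethylation list, HMCES, which binds abasic sites, at -0.25 (0.023) and the DNA ligase LIG3 at -0.26 (0.028). The count of 8 was between 0 and 4 whichever array was left out. It was 0 without either array of TET1-A or TET3-C, the uninduced array of TET1-G, the induced array of TET3-A or TET3-B, or clone TET1-A, TET1-G, TET3-A, TET3-B or TET3-C. It was 1 without the induced array of TET1-F or TET1-G or the uninduced array of TET3-B, 3 without the uninduced array or both arrays of TET1-F, and 4 without the uninduced array of TET3-A. The blocked count was 166, 49, 114, 130 and 62 without clone TET1-A, TET1-F, TET1-G, TET3-B and TET3-C.

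Of the gene lists, 9 passed for the mean of both inductions. Upward shifts were seen for the unfolded protein response (26 of 31 higher, median 0.11, camera adjusted p = 9e-06; adjusted p = 0.23 with an estimated correlation), and ATF4 targets (38 of 51 higher, median 0.10, adjusted p = 0.0011; adjusted p = 0.51 with an estimated correlation). They were also seen for G2/M genes (49 of 68 higher, 0.0051; adjusted p = 0.64 with an estimated correlation), mitochondrially encoded genes (6 of 7 higher, 0.014; adjusted p = 0.51 with an estimated correlation) and cholesterol and fatty acid synthesis (19 of 28 higher, 0.045; adjusted p = 0.33 with an estimated correlation). Downward shifts were seen for interferon-stimulated genes (25 of 34 lower, median -0.20, adjusted p = 5.1e-04; adjusted p = 0.19 with an estimated correlation) and HOX genes (18 of 25 lower, 0.014; adjusted p = 0.33 with an estimated correlation). The other downward ones were kidney epithelium markers (12 of 15 lower, 0.024; adjusted p = 0.23 with an estimated correlation) and cytosolic ribosomal proteins (49 of 52 lower, 1e-06; adjusted p = 0.64 with an estimated correlation), the last turning direction with quantile normalization. Adjusted over the list alone, 3 unfolded protein response, 2 mitochondrially encoded and 2 cholesterol synthesis genes rose and 1 interferon-stimulated gene fell. With the block, Wnt targets, TGF-beta targets and histone genes passed too (adjusted p = 0.047, 0.039 and 0.018, against 0.057, 0.073 and 0.11 without it; adjusted p = 0.28 each with the block and an estimated correlation). The unfolded protein response, ATF4 and interferon lists kept their calls in all 27 other settings at the preset correlation. The count of 9 became 4 without the induced array of TET1-G and 5 without the induced array of TET3-A. The HOX and kidney lists lost their calls without either of those arrays or the uninduced array of TET1-F, and the kidney list also without the uninduced array of TET3-C or clone TET1-G or TET3-C (highest adjusted p 0.094 and 0.13). The G2/M list lost its call without the induced array of TET1-G or the uninduced array of TET1-F (0.36), and the ribosomal list without clone TET3-B (0.70). The mitochondrially encoded list lost its call without the induced array of TET1-F, TET1-G or TET3-A, the uninduced array of TET1-A or TET3-B, or clone TET1-G or TET3-A (0.11). The cholesterol list kept its call in 14 of 27 settings (0.15).

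Between the inductions little correspondence was seen over all probe sets. Across the 30191 probe sets, which are not independent replicates, the TET1 and TET3 fold changes correlated at Pearson r = 0.0529 and Spearman rho = 0.113. The inductions share no array. Of the 221 probe sets past the threshold for TET3 with the clone as a block, 184 (83.3%) had the same sign in the TET1 clones, against 55.8% of all tested. Their median log2 change in the direction of the TET3 change was 0.136 in the TET1 clones and 0.453 in the TET3 clones. The 221 were chosen by their TET3 change, which raises the TET3 median alone, so these 2 sizes are not comparable. Over the 436 probe sets other than TET3 called for the mean with the block, the medians were 0.258 for TET1 and 0.321 for TET3. The correlation was 0.261 with the stricter filter and 0.0167 with no filter, and it was 0.035 without the induced array and 0.029 without both arrays of TET1-F.

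**Figure D3:**
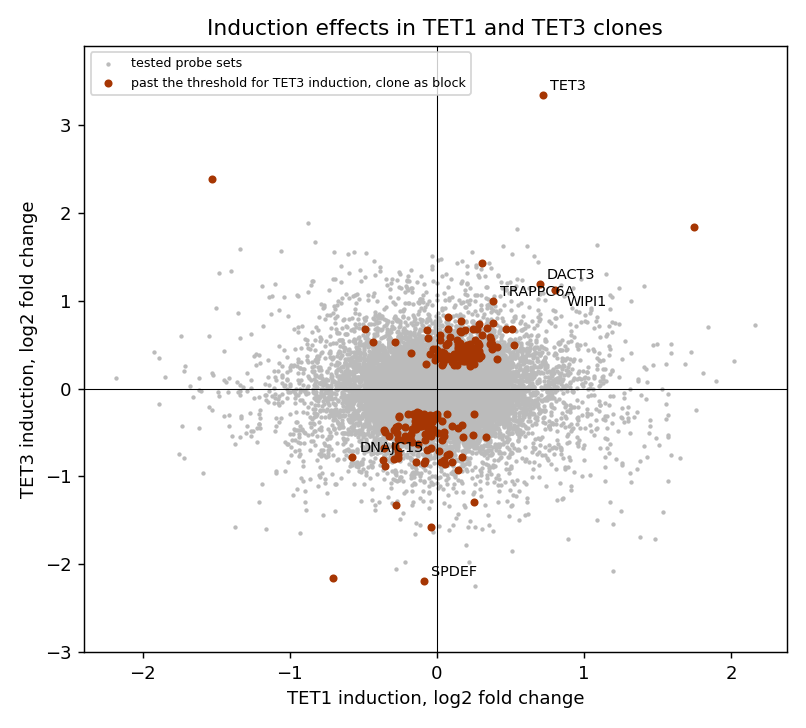
Log2 fold change on TET3 induction against that on TET1 induction, with 1 grey point per tested probe set (30191) and filled points for the 221 past the threshold for TET3 induction with the clone as a block. Of the filled points 184 lie in the quadrants where both changes share a sign.

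The difference between inductions was tested directly and gave 0 of 30191 probe sets by limma. At an unadjusted p of 0.05 there were 1237, fewer than the 1510 expected without any change. That fit leaves the differences between clones in the spread. With the clone as a block there were 2514, more than the 1510. TPM4, a tropomyosin, was the 1 probe set past the threshold with the clone as a block (TET3 effect minus TET1 effect 0.97 on the log2 scale, SE 0.12, adjusted p = 0.0496), and was chosen after its values were seen. Leaving out the uninduced array of TET1-G or clone TET1-G gave 1 call. At the level of lists, 5 differed. Keratinocyte and HeLa-type markers had a lower response in the TET3 clones (9 of 10 members, median difference -0.33, camera adjusted p = 0.0014; adjusted p = 0.31 with an estimated correlation), and HOX genes did too (21 of 25, median -0.16, adjusted p = 0.013; adjusted p = 0.55 with an estimated correlation). Examples are KRT19 at -0.28, CAV1 at -0.35 and HOXD1 at -0.99 (SE 0.13, 0.13 and 0.33, adjusted p = 1 each). Cholesterol and fatty acid synthesis genes had a higher response in the TET3 clones (21 of 28, median 0.09, adjusted p = 0.0056; adjusted p = 0.31 with an estimated correlation), for example ACAT2 at 0.39 (SE 0.11, adjusted p = 1). Oxidative phosphorylation genes (54 of 68, median 0.05, adjusted p = 0.0056; adjusted p = 0.89 with an estimated correlation) and cytosolic ribosomal proteins (51 of 52, median 0.08, adjusted p = 1.6e-06; adjusted p = 0.74 with an estimated correlation) also had a higher response. Quantile normalization ended both calls and turned the direction of the ribosomal proteins. The ACTB ratio also moved in opposite directions, lower after TET1 and higher after TET3 induction. No member passed in any of the 5 lists, over all probe sets or adjusted over the list alone. With the block 9 lists passed, adding developmental transcription factors, G2/M genes, the unfolded protein response and TGF-beta targets (adjusted p = 0.046, 0.012, 0.024 and 0.026, against 0.071, 0.089, 0.053 and 0.17 without it). With the block and an estimated correlation they had an adjusted p of 0.57, 0.57, 0.47 and 0.47. The count of 5 was 2 without the induced array of TET3-A or without clone TET3-A, 3 without clone TET3-C, 8 without the uninduced array of TET1-F, the induced array of TET3-B or clone TET3-B, and 9 without clone TET1-F. The HOX list lost its call without the induced array of TET1-F or TET3-A, the uninduced array of TET1-G, or clone TET1-G, TET3-A or TET3-C (highest adjusted p 0.13). The cholesterol list lost it without the induced array of TET1-A or TET3-A (0.066), the ribosomal list without the induced array of TET3-A or clone TET3-A, and the epithelial list with no filter (0.22). The oxidative phosphorylation list lost it without the induced array of TET1-F or TET3-A, the uninduced array of TET1-A, TET1-G or TET3-A, or clone TET3-A or TET3-C (0.60).

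The largest contrast lay between the uninduced clones of the different transgenes, where 4689 of 30191 probe sets passed, 2097 higher in the TET3 clones and 2592 higher in the TET1 clones. That balance turned with quantile normalization, to 2409 and 2346. Apart from TET3 itself, a probe set of LTAP1 was higher in the TET3 clones, at 6689 ± 534 against 1761 ± 369 (n = 3 each), with a log2 difference of 1.93 (SE 0.12, adjusted p = 1.4e-06). The brightest LTAP1 probe set did not differ past the threshold (-0.04, adjusted p = 0.75). The transcription factor USF1 stood at 1.92 and CHSY3 at 1.86, with means of 122.5 and 132.9 in the TET1 clones. The other genes named by rule rest on probe sets below the median signal of every array in the TET1 clones, so the size of their difference depends on the added 16. They were ANAPC13, a subunit of the anaphase-promoting complex, with 2.16 (14.9 against 113.3 in the TET3 clones), BMS1P20 with 2.08 (35.66 and 191.8), POLE4 with 1.82 (45.45 and 160.7) and VPS53 with 1.82 (42.43 and 156.3). Adjusted p for these 6 genes lay between 0.0027 and 0.036. The brightest probe set of ANAPC13 stood at 0.11 (adjusted p = 0.43), that of BMS1P20 at -0.44 (0.04), that of POLE4 at 0.52 (0.0053) and that of VPS53 at 0.19 (0.44). Lower in the TET3 clones were the surface protein CD99 with -3.20 (SE 0.76, adjusted p = 0.011) and SCARA5 with -2.35 (SE 0.45, adjusted p = 0.0033). The other lower genes had means below every array's median in the TET3 clones, so their size depends on the added 16 too. They were B3GALNT1 with -3.47 (343.7 in the TET1 and 18.44 in the TET3 clones), SNCAIP with -2.90 (468.4 and 55.15), RIPPLY3 with -2.87 (424.9 and 50.33), P-cadherin CDH3 with -2.85 (442.9 and 44.17), the mitochondrial folate enzyme ALDH1L2 with -2.36 (381.3 and 64.84) and MELTF-AS1 with -2.29 (178.6 and 20.21), with adjusted p between 3e-04 and 0.028. CD99 read 5148 ± 3e+03 in the TET1 and 731.9 ± 674 in the TET3 clones (n = 3 each). Of the demethylation list, IDH2, whose mutant forms block TET enzymes, was lower in the TET3 clones at -1.25 (SE 0.12, adjusted p = 3.7e-05). The thymine DNA glycosylase TDG was higher at 0.34 (SE 0.05, adjusted p = 8.8e-04), although the list as a whole did not pass (adjusted p = 0.84). Clone sets and transgenes coincide here, so any difference in the origin or handling of the sets falls into this contrast. The ACTB 3' to 5' ratio lay between 1.90 and 2.05 on all 6 TET3 arrays and between 2.09 and 2.39 on all 6 TET1 arrays (exact permutation test, two-sided, p = 0.0022, over 924 splits that treat paired arrays as separate), whereas that of GAPDH overlapped (exact permutation p = 0.38). The transgene differs between clones and not between the arrays of a clone, so the p for ACTB overstates the evidence. The count was 2811 without clone TET3-B and 2790 without clone TET3-C. ANAPC13, POLE4, VPS53 and MELTF-AS1 lost their calls without 1 array or clone in several cases, with an adjusted p of at most 0.095, 0.15, 0.15 and 0.15.

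Between the uninduced clones 10 lists passed. ATF4 targets of the integrated stress response were lower in the TET3 clones in 46 of 51 members. Past the threshold over all probe sets 30 fell, and adjusted over the list alone 44 fell and 1 rose, with a median log2 difference of -0.57 (camera adjusted p = 6.6e-15; adjusted p = 0.23 with an estimated correlation). They included DDIT4, an inhibitor of mTOR signalling, at -2.00 (SE 0.09, adjusted p = 2e-08), the mitochondrial PEP carboxykinase PCK2 at -1.60 (SE 0.15, adjusted p = 3.6e-05) and cystathionine lyase CTH at -1.37 (SE 0.13, adjusted p = 2.6e-05). Lower too were asparagine synthetase ASNS at -1.09 (SE 0.08, adjusted p = 5.4e-06) and the serine synthesis enzyme PHGDH at -0.76 (SE 0.08, adjusted p = 8.9e-05). Ribosome biogenesis genes were higher in 35 of 39 members, of which 18 rose past the threshold (median 0.28, adjusted p = 3.6e-10; adjusted p = 0.054 with an estimated correlation), for example GRWD1 at 0.94 (SE 0.12) and UTP14A at 0.77 (SE 0.09). Mitochondrial ribosome and translation genes were higher in 53 of 68, of which 21 rose (median 0.17, adjusted p = 1.1e-08; adjusted p = 0.36 with an estimated correlation), for example MRPL27 at 0.64 (SE 0.09). In contrast, 5 of 7 mitochondrially encoded genes fell (median -0.49, adjusted p = 0.0012; adjusted p = 0.36 with an estimated correlation), for example ND4 at -0.99 (SE 0.09).

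In the unfolded protein response list 10 of 31 members were higher and 2 lower in the uninduced TET3 clones, and 19 did not pass (adjusted p = 0.0011; adjusted p = 0.36 with an estimated correlation), with, for example, the chaperones HSPA5 at 0.89 (SE 0.10) and DNAJB11 at 0.78 (SE 0.10) higher and the sensor ERN1 at -0.90 (SE 0.13) and HERPUD1 at -0.80 (SE 0.16) lower. Of 21 heat shock proteins 6 were higher, 1 was lower and 14 did not pass (adjusted p = 0.0011; adjusted p = 0.31 with an estimated correlation), with DNAJA1 at 1.07 (SE 0.09) and HSPH1 at 0.61 (SE 0.07) higher and HSPB1 at -0.96 (SE 0.24) lower. KRAB zinc finger genes had 14 higher and 6 lower members (adjusted p = 0.0067; adjusted p = 0.36 with an estimated correlation). Hypoxia response and glycolysis genes had 2 higher and 13 lower (adjusted p = 0.015; adjusted p = 0.31 with an estimated correlation), for example VEGFA at -0.78 (SE 0.12) and PDK1 at -0.76 (SE 0.13). Fibroblast markers had 5 lower (adjusted p = 0.018; adjusted p = 0.23 with an estimated correlation), for example LOX at -0.58 (SE 0.11) and TWIST2 at -0.65 (SE 0.14). All single genes given here passed the threshold, HSPB1 not without the uninduced array or both arrays of TET1-A (adjusted p = 0.066 and 0.069). Cytosolic ribosomal proteins were lower in 51 of 52 members (adjusted p = 7e-04; adjusted p = 0.72 with an estimated correlation), with RPL12 at -0.19 (SE 0.06, adjusted p = 0.039) alone past the threshold and none adjusted over the list alone. The list lost its call with quantile normalization and median centring, and RPL12 with both of these and without several single arrays. Adjusted over the list alone, the higher and lower members were 18 and 0 for ribosome biogenesis, 22 and 0 for the mitochondrial ribosome, 0 and 6 for mitochondrially encoded genes, 10 and 3 for the unfolded protein response, 8 and 1 for heat shock proteins, 16 and 6 for KRAB genes, 2 and 19 for hypoxia and 0 and 5 for fibroblast markers. The lists without a leave-out named here kept their calls in all 25 other settings at the preset correlation, the ribosomal proteins apart. The KRAB list lost its call without the uninduced array or clone of TET3-A (highest adjusted p over all settings 0.067), the hypoxia list without those of TET3-C (0.058) and the fibroblast list without clone TET1-F or the filter (0.11).

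**Figure D4:**
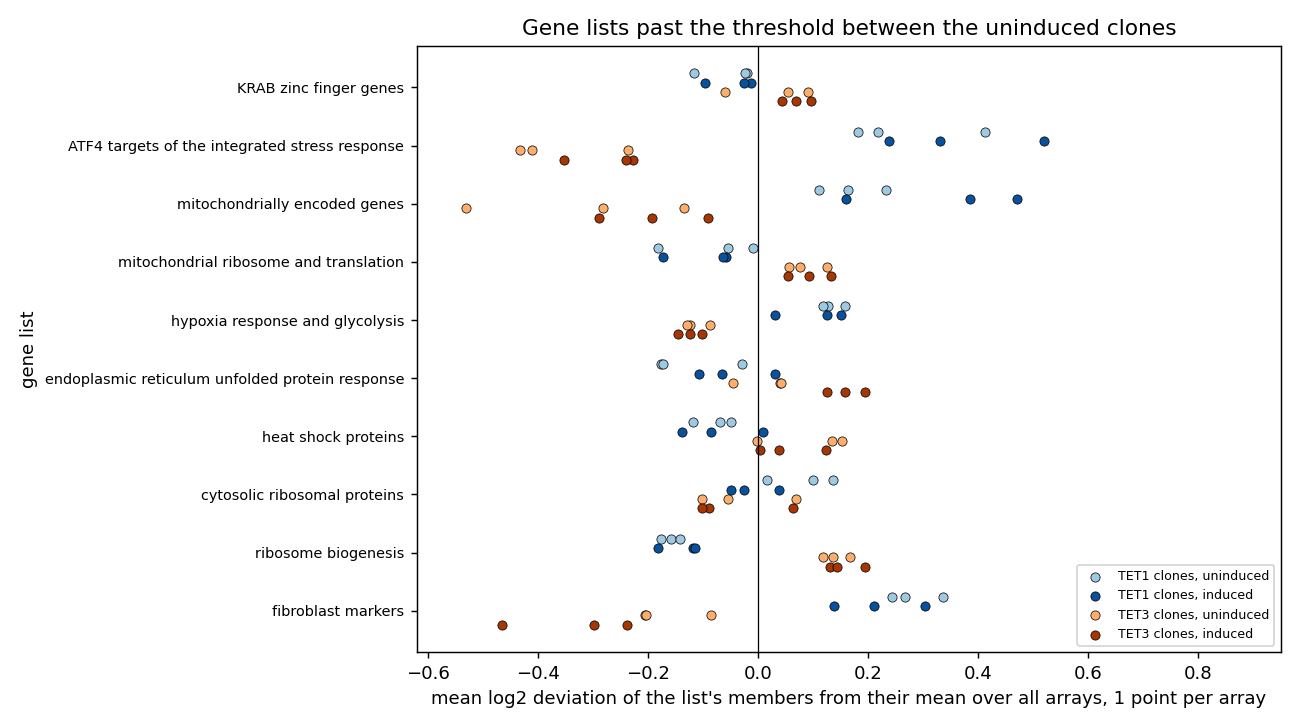
Mean log2 deviation of each list's members from their mean over all arrays, with 1 point per array and colours for the 4 groups of 3 arrays. ATF4 targets stand between 0.181 and 0.52 on the 6 TET1 arrays and between -0.433 and -0.227 on the 6 TET3 arrays, and ribosome biogenesis genes stand below 0 on all TET1 arrays and above 0 on all TET3 arrays.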

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

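The tests of endogenous TET3, of transcription without doxycycline, of separate handling and of the authors' scaling, and the fit without the block over all splits that part every pair (probe sets of the mean, and the correlation), were chosen only after the results were seen.

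In tests of the difference between TET1 and TET3 induction, 5 gene lists passed at the preset correlation and, with the clone as a block, 1 probe set. None of the 5 passed with an estimated correlation (adjusted p from 0.31 to 0.89), and 48 of 100 splits and 13 of the 32 that part every pair gave 5 or more, so chance cannot be excluded for them. Keratinocyte and HeLa-type markers (camera adjusted p = 0.0014) had per-clone medians between 0.13 and 0.17 in the TET1 clones and between -0.28 and -0.17 in the TET3 clones. The other lists were HOX genes (0.013), cholesterol and fatty acid synthesis (0.0056), oxidative phosphorylation (0.0056) and cytosolic ribosomal proteins (1.6e-06), the last with a direction that turned under quantile normalization. TPM4 (adjusted p = 0.0496 with the block, 0.53 without) had log2 changes of -0.35, -0.445 and -0.517 in TET1-A, TET1-F and TET1-G and of 0.561, 0.498 and 0.529 in TET3-A, TET3-B and TET3-C.

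The TET3 probe set that rose on induction was already 4.33 higher (log2) in uninduced TET3 than in uninduced TET1 clones. Higher endogenous TET3 mRNA is argued against by the other TET3 probe sets, whose larger difference was 0.293. That reading assumes that they see the endogenous transcript at the same rate, and the difference had an adjusted p of 0.097. Transcription of the transgene without doxycycline is a candidate explanation that stays open: the uninduced signal was 12.9%, 6.52% and 10.6% of the induced one in TET3-A, TET3-B and TET3-C, with a median of 10.6%. Some induced RNA in the uninduced samples would give the same values, so the explanations cannot be told apart.

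The uninduced TET3 and TET1 clones differed in 4689 probe sets, and 4688 of them, without the TET3 probe set, were used here. A TET3 effect that grows with the TET3 level would carry the TET3 induction further along this difference, but the slope of the induction on the difference of the other clones was -0.031 on average over 3 clones (SD 0.014). An effect already saturated at the uninduced level stays open. RNA quality as read by the ACTB ratio is argued against as the whole cause. TET1 induction closed 0.47 of the ratio's gap, while its slope on the difference was 0.028 (SD 0.0096). The probe sets were chosen with the uninduced array of the tested clone included. That choice by itself pulls the TET3 slope down and the TET1 slope up, by an amount not measured. The TET3 slope therefore weighs less against a growing TET3 effect, and slopes this small are not read as movement. Separate handling of the clone sets cannot be told apart from clone origin or a lasting transgene effect, since all 12 arrays lay on their own transgene's side of the first principal component.

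With the clone as a block, 437 probe sets changed in the mean of both inductions, 436 of them other than TET3. The authors' scaling is argued against as the whole cause, since 548 probe sets passed with quantile normalization and the block, with 429 of the 437 among them. Median centring gave 208, with 187 of the 437 among them. The 250 calls it ended had a median size of change of 0.238 (median SE 0.047) before and 0.241 (median SE 0.066) after centring, so they ended because the spread grew and not because the change shrank. An effect of doxycycline of equal size in both sets may be the cause of part of these changes. The median TET3 effect exceeded the TET1 effect by 0.0934 on the log2 scale (0.0811 to 0.105 without 1 clone), beside a median change of 0.284. Of the 436, 117 (26.8%) differed at an unadjusted p of 0.05, against 2514 of all 30191 in the same fit. The 436 were called with the same estimate of the spread, which favours probe sets of small spread, so this share does not test the explanation. Without a doxycycline-treated line free of transgenes, an effect of doxycycline cannot be told apart from an effect of both TET proteins.

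Other splits of the same arrays were run for each count. For the mean of both inductions the splits argue against chance for the probe sets but do not exclude it. Of the 32 splits that part every clone's pair, as the real one does, 1 gave 8 or more, the real one (highest other 0). With the block 1 gave 437 or more (highest other 13). A share of 1 in 32 is the smallest that these splits can give. Among 100 splits that mostly do not part every pair, 1 gave 8 or more (highest other 5). For the correlation of 0.0529 between inductions, 1 of the 32 was as high, the real one (highest other 0.0366), and 6 of the 100 were as high (highest other 0.0856). Exchanging the labels in all clones of 1 transgene turns the sign of this correlation, so another of the 32 splits has the same size. Chance therefore cannot be excluded for the correlation. Chance cannot be excluded for the mean's 9 lists (9 of 100 splits, highest other 13; 4 of 32, highest other 12) or for the 5 lists of the difference (highest other 12 among the 100 and 12 among the 32). The difference's 0 probe sets (limma found 1237 at an unadjusted p of 0.05) are matched by every split, 100 of 100, so the splits do not test that count. The highest others were 5, and 8 among the 32. The 100 were drawn from 200 splits within both clone sets. Exchanging the labels in all clones of 1 transgene turns the difference into the mean, and that split is among the 32.

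Within 1 set of clones the splits are too few for a share under 0.05. In TET3 induction 1 of 10 gave 2 or more probe sets (highest other 1), 2 of 10 gave 9 or more lists (highest other 10) and with the block 1 of 4 gave 221 (highest other 0). In TET1 induction the real count of 0 (limma, 1770 at an unadjusted p of 0.05) is matched by every split, 10 of 10, and so is not tested by them (highest other 4), and 5 of 10 gave 5 or more lists (highest other 8). Of the 4 splits that part every pair, the highest others were 0 probe sets and 10 lists for TET3 and 0 probe sets and 2 lists for TET1. Between uninduced clones 1 of 10 gave 4689 (highest other 1) and 3 of 10 gave 10 or more lists (highest other 10).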

How the results depend on the processing

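The alternatives for the blocked counts and for the lists between uninduced clones were chosen only after the results were seen, and the other alternatives were fixed in advance. Where a value moved, the cause was not tested unless given.

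No named gene's change past the threshold reversed. The balance between uninduced clones turned from 2097 higher and 2592 lower in the TET3 clones to 2409 and 2346 with quantile normalization, and the cytosolic ribosomal protein lists of TET1 induction, the difference and the mean turned direction without a call under quantile normalization. With the clone as a block, TET1 induction gave 1 probe set, TET3 induction 221 in place of 2, the difference 1 and the mean 437 in place of 8, and lists that differed were 9 in place of 5. With the block and quantile normalization these probe set counts were 14, 216 and 548 for TET1, TET3 and the mean, with 3 lists for TET1 and 14 for TET3. The block removes differences between clones and leaves 4 residual degrees of freedom in place of 8.

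For TET3 induction (2) the count was 1 with a pseudocount of 1, 8 with the stricter filter, 0 without an intensity trend, 5 with 1 probe set per gene, 27 with array weights and 1 with only the arrays of the groups compared. For the mean (8) it was 0 with a pseudocount of 1, 18 with quantile normalization, 3 with median centring, 0 with no filter, 15 with the stricter filter, 0 without a trend and 21 with array weights. These counts of 0 are limma's, and the main settings gave 1980 and 2476 at an unadjusted p of 0.05. Between uninduced clones (4689) 1 probe set per gene gave 2751, with fewer probe sets tested. The TET3 transgene's log2 fold change was 3.38 with a pseudocount of 1 and 3.34 without a trend, past the threshold in neither.

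The correlation between inductions (0.0529) was 0.0413 and 0.0802 with pseudocounts of 1 and 64, 0.0167 with no filter, 0.261 with the stricter filter, 0.0844 with 1 probe set per gene and 0.0429 with array weights. It was higher the more dim probe sets the filter removed.

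Lists past the threshold were 0 for TET1, TET3, the difference, the mean and the uninduced clones with an estimated correlation. With quantile normalization they were 3 for TET1 and 3 for the difference, and for the difference also 8 with median centring, 9 with the stricter filter and 3 with the mean of a gene's probe sets.

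Leaving out 1 array or clone gave 0 to 6 probe sets for TET3, 0 to 1 for the difference, 0 to 4 for the mean and 2790 to 4966 between uninduced clones, a correlation of 0.029 to 0.0656, and a TET3 fold change of 3.04 to 3.61. Lists ranged from 2 to 7 for TET1, 5 to 13 for TET3, 2 to 9 for the difference, 4 to 12 for the mean and 9 to 11 between uninduced clones. TET1 induction stayed at 0.

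The blocked counts were 114 and 208 for TET3 and the mean with median centring, 130 and 219 with no filter and 344 and 760 with the stricter filter. Without 1 clone they were 12 to 58 and 49 to 370. Quantile normalization kept 192 of 221 and 429 of 437 of these calls and 4253 of 4689 between uninduced clones, and median centring 106, 187 and 3490. Higher in the TET3 clones were 44.7% of the uninduced calls, 50.7% with quantile normalization and 49.9% with median centring.

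Among the named genes past the threshold 46 of 53 kept their call between uninduced clones in every setting, 0 of 2 in TET3 induction and 0 of 6 in the mean by limma, and all kept their direction. More named genes than those given with the comparisons passed only with the block. For the mean they include PDLIM2 (adjusted p = 0.055 without and 0.0064 with it), EFEMP1 (0.12 and 0.0097), MFAP2 (0.18 and 0.01), DACT3 (0.055 and 0.013), CNTNAP2 (0.19 and 0.021), MPV17L2 (0.086 and 0.022), PLPP4 (0.15 and 0.039) and ADK (0.19 and 0.04), and HOXC4, ADAR, NEK2 and SPC25 (0.033, 0.04, 0.04 and 0.028 with it). Probe sets above the array's median on fewer than 3 of the 12 arrays were not tested, and the added 16 shrinks the change of dim probe sets.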

Other observations

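The tests behind these values were fixed in advance, and none was chosen only after a result was seen, but the genes described here were picked from the named ones afterwards.

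Of 19 genes of DNA methylation maintenance and readers, 2 were higher and 3 lower in the uninduced TET3 clones, 14 did not pass, and the list was not past the threshold (adjusted p = 0.47). UHRF1, which guides maintenance methylation, was higher in the TET3 clones at 0.36 (log2, adjusted p = 0.0053), and CDCA7, a cofactor of a chromatin remodeller needed for methylation, was lower at -0.51 (adjusted p = 2.7e-04). GADD45A, of the demethylation list, was lower at -0.69 (adjusted p = 0.0028). Among imprinted genes CDKN1C was lower at -0.97 (adjusted p = 0.0074) and GRB10 at -0.43 (adjusted p = 0.004), while the imprinted list did not pass (adjusted p = 0.32).

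The dimmer TET1 probe set was lower after induction of either transgene, with a mean log2 change of -0.47 that passed with the clone as a block (adjusted p = 0.044) and not without (0.53). The brighter TET1 probe set did not pass in the same fit (-0.15, adjusted p = 0.21). In the same fit the histone gene H2BC12 fell at -0.24 (adjusted p = 0.015) and VEGFA rose by 0.22 (adjusted p = 0.04).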
